A study of Clostridium acetobutylicum with 8 samples.

How the data were processed

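Gene expression was measured in Clostridium acetobutylicum B3, a solvent-producing anaerobic bacterium, grown either as a biofilm on a cotton carrier or as free planktonic cells. Cells of both modes were taken at 4 phases of the fermentation, and 8 one-colour (Cy3) Agilent arrays were analysed here, 1 for each mode and phase. The series describes an experiment done more than once, but a second set of arrays was not analysed here, so every group holds 1 array.

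The authors deposited scanner output as spot intensity, made with Agilent Feature Extraction 10.7.3.1 per the file headers (10.7 per the submitters' processing notes), with background correction and spatial detrending already in the processed signal. The authors also deposited a value table, which holds log2 values. Its 8 columns had 1 median, 5.32, and 1 range, which is the mark of quantile normalization, and it was not centred on genes. The scanner signals settled its scale, centring and direction. Its entries were matched to the scanner output through the probe names. Each array held 15739 spots, of which 15203 were not controls, from 8263 distinct probes. Of these probes, 4188 carried coordinates on 3 sequence records, which the files name by number alone and which are called A, B and C here. Record A had 3671 probes, record B 201 and record C 316, and no genome build or strain is given for them. All 3819 distinct sequences came from intervals whose length is a multiple of 3, and the intervals are called coding sequences for that reason. The other 4075 probes had no coordinates and entered none of the fits; their signals are described with the additional observations.

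The files give no gene names for these probes, and no table of names was used here. The gene lists fixed before the data were examined, which named genes by locus tag or product, were therefore void, as was the panel of named solvent and acid genes. In their place, after the probe annotation was read and before any arrays were compared, operon-like runs were defined as at least 3 neighbouring coding sequences of record A on the same strand with gaps of at most 50 bp. Runs are named by start and end.

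Signals were taken as log2 of the processed signal minus the 75th percentile of each array over the 5670 non-control spots well above background on all 8 arrays, because between 42.7% and 54.3% of the spots of an array were well above background. Outlier spots were left out. Probes with identical sequence were averaged, which gave 3819 features, 360 of them with more than 1 spot. Features well above background on at least 4 of the 8 arrays were tested, 3725 in all. Runs with at least 3 tested members numbered 288 and held 1229 features.

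Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes variances and Benjamini-Hochberg adjustment, with a threshold of 0.05. The biofilm minus planktonic difference was fitted with phase as a 4-level block, because the design sets the modes against each other within a phase. The error of that fit is the variation of the difference from phase to phase, with 3 residual degrees of freedom. Phase effects came from the same fit. The change of the difference from phases 1 and 2 to phases 3 and 4 was fitted as an interaction, with 2 residual degrees of freedom. Within a phase no test was possible, and log2 differences and counts of features differing at least 2-fold were described. Runs were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and also with the run mean as 1 value per array in limma. Arrays carry no sequencing depth, and their number limits the precision.

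Runs named for the mode comparison were the 5 largest mean rises and 5 largest mean falls among those past the camera threshold with 1 direction in all 4 phases. For phase 4 against phase 1 they were the 3 largest each way among those past the camera threshold. Both rules were written together with the definition of the runs. For each phase the 3 largest differences each way were named, a rule for genes that was carried over to runs. Of single features, only the 2 with the largest mean difference among those past the limma threshold are named, because their identifiers cannot be paired with gene names. A feature not well above background has only a bound, and folds that involve one are written as "at least", computed against the lowest signal of features well above background on the same array or the feature's own signal, whichever was higher.

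The fits were tested on simulated data with 200 of 3725 features changed. For the mode difference, 66.5% of features changed 2-fold, 95.0% of those changed 4-fold and 99.0% of those changed 8-fold were recovered. In the same order, 12, 7 and 13 unchanged features were called falsely. For phase 4 against phase 1, 0 of 200 features changed 2-fold and 92.5% of those changed 4-fold were recovered. For the interaction, 0 of 200 changed 2-fold and 65.0% changed 4-fold were recovered. At 4-fold, 9 unchanged features were called falsely for phase 4 against phase 1 and 13 for the interaction. Among 20 of 288 runs changed 8-fold in the modes, camera with the preset correlation recovered 20 and camera with an estimated correlation 0, so the latter had no power in this design. The simulated noise was independent between features, which flatters the tests of runs. It was drawn from the empirical Bayes variances of the fit, and planted mode changes were equal in all 4 phases, unlike real ones. The recovered shares therefore do not give the share of real differences that was found. In the real mode fit, the smallest mean log2 difference called was 1.50.

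All 8 arrays lay on 1 slide in 2 rows. The biofilm and planktonic arrays shared a row in phases 1 and 2 and lay in different rows in phases 3 and 4, always the same way round. Slide row and the late minus early change of the biofilm difference therefore cannot be told apart. Alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' value table, no filter (all features with coordinates) or a filter on all 8 arrays, the brightest probe per feature, leaving out each phase pair, no phase block, slide row as a further block, trended and robust variances, and a 3-fold threshold. The percentile over all non-control spots, the run mean in limma and all alternatives for runs were added after the data were seen.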

Results

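The 8 arrays covered biofilm and planktonic cells at acidogenesis (phase 1, 10 h), the transition phase (phase 2, 15 h), early solventogenesis (phase 3, 20 h) and late solventogenesis (phase 4). Phase 4 was sampled at 25 h in the biofilm and at 34 h in planktonic cells, so the modes differ in hours there. Acidogenesis is the stage in which this bacterium forms acetate and butyrate, and solventogenesis the stage in which it forms acetone, butanol and ethanol. Of the 3819 features with coordinates, between 96.4% and 97.7% were well above background on each array. Their median signal ranged from 580 on the biofilm array of phase 1 to 1022 on the planktonic array of phase 2, and 0 spots were saturated. Among 351 pairs of spots with identical sequence, the technical SD of the biofilm minus planktonic difference was between 0.22 and 0.25 on the log2 scale. There were no replicates within a mode and phase. The p-values measure the spread of the difference over phases and say nothing of the spread between cultures.

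The first comparison asked which genes differed between biofilm and planktonic cells of the same phase. Over the phases, 8 of 3725 features were higher in the biofilm and 0 were lower (limma with phase as a block, adjusted p under 0.05), while 784 had an unadjusted p under 0.05. A limma fit with trended and robust variances called 12 higher and 0 lower, and scaling to the percentile over all non-control spots gave 14 higher and 2 lower. A coding sequence on the plus strand of record B (645595 to 645786) was higher in the biofilm, with a mean log2 difference of 3.42 ± 0.46 (SD over 4 phases, limma adjusted p = 0.0124). A coding sequence on the plus strand of record A (680364 to 680792) was 8.70-fold higher, with a mean log2 difference of 3.12 ± 0.29 (SD over 4 phases, limma adjusted p = 0.0102). The remaining 6 features had mean log2 differences of up to 2.62 and limma adjusted p between 0.0274 and 0.0337. Of the 8 features, 4 formed 2 pairs of neighbours on the same strand with gaps of 0 and 18 bp. In all, 6 lay on record A and 2 on record B. Whether features on different records stand for the same coding sequence was not checked, so features are not a count of genes. All 8 were higher in the biofilm in all 4 phases, with single differences between 1.31 and 3.90. When a phase pair was left out, 2 features passed without phase 1 and 0 passed without phase 2, phase 3 or phase 4. With slide row as a further block 0 passed, and without the phase block 4 did. The pairs of phases 1 and 2 each lay within 1 slide row, and all 8 features were higher in the biofilm in both. The 8 were called on these same differences, so their direction there is no separate test of slide row.

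Among operon-like runs, a run of 4 coding sequences on the plus strand of record A (370955 to 375566) was higher in the biofilm in every phase, with log2 differences of 2.08, 2.40, 1.16 and 2.24 in phases 1 to 4. A run of 3 on the plus strand (439419 to 441714) had a mean log2 difference of 2.79 ± 2.14 (SD over 4 phases), from 0.58 in phase 3 to 5.02 in phase 4. A run of 5 on the minus strand (3836318 to 3840429) had a mean difference of 1.55 ± 1.09, and 5 of 5 members were higher. A run of 4 on the minus strand (1274369 to 1277118) was higher by 1.12 in phase 1 and 3.75 in phase 2, and a run of 5 measured sequences on the minus strand (1290943 to 1294722) by 1.19 and 3.30. From phase 3 on, all 4 members of the former and some of the latter were not well above background in the mode with the lower signal, and no fold is given there. On the lower side, a run of 6 on the plus strand (3824260 to 3828397) had differences of -2.73, -1.77, -0.99 and -0.80 in phases 1 to 4, with 6 of 6 members lower in the mean. Runs on the minus strand at 2457890 to 2462128, 3213138 to 3218047, 3033758 to 3036404 and 2454438 to 2457759 had mean log2 differences of -0.83 ± 0.49, -0.79 ± 0.30, -0.68 ± 0.34 and -0.55 ± 0.26 (SD over 4 phases). Camera with the preset correlation called 25 of 288 runs higher and 16 lower. With an estimated correlation camera called 0 runs and gave an adjusted p of 0.874 for each of these 10 runs. That setting recovered 0 of 20 simulated runs, so its outcome does not weigh on these calls. The run mean in limma called 0 runs, with 70 at an unadjusted p under 0.05 and a smallest adjusted p of 0.125. Camera at the preset correlation called 41 runs for the real pairing and up to 55 when the modes of some phases were exchanged, so the run differences are described and not called.

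**Figure D1:**
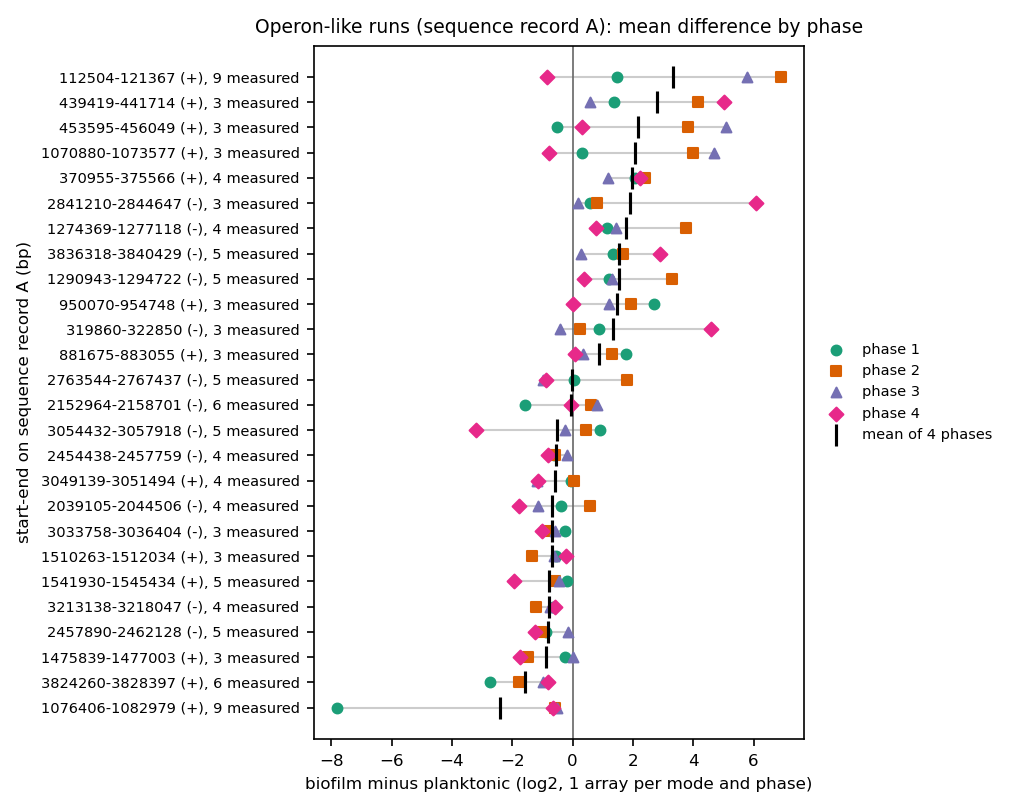
Mean log2 difference, biofilm minus planktonic, of the operon-like runs named for the mode comparison or for a phase; the y axis gives start and end on record A with the strand, coloured points are the 4 phases (1 array per mode and phase) and the black bar is their mean. The run 370955 to 375566 stays between 1.16 and 2.40, whereas 1076406 to 1082979 lies at -7.82 in phase 1 and at -0.59, -0.52 and -0.66 in phases 2, 3 and 4.

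Within phases, pairs of single arrays were compared without a test. In phase 1, the run of 9 coding sequences on the plus strand at 1076406 to 1082979 was 227-fold lower in the biofilm, with a log2 difference of -7.82 and all 9 members lower, while its differences in phases 2, 3 and 4 were -0.59, -0.52 and -0.66. Runs of 3 on the plus strand at 950070 to 954748 and 881675 to 883055 were higher in the biofilm in phase 1 by 2.71 and 1.78, and a run of 6 on the minus strand at 2152964 to 2158701 was lower, at -1.57. In phases 2 and 3, a run of 9 on the plus strand at 112504 to 121367 was 121-fold and 55.3-fold higher in the biofilm, with log2 differences of 6.92 and 5.79 after 1.47 in phase 1 and before -0.83 in phase 4. In the same phases a run of 3 on the plus strand at 1070880 to 1073577 was higher by 4.00 and 4.70, and a run of 3 at 453595 to 456049 by 3.84 and 5.09. Lower runs were less far apart in these phases. Those on the plus strand at 1475839 to 1477003 and 1510263 to 1512034 were at -1.47 and -1.35 in phase 2. Those at 3049139 to 3051494 and 2763544 to 2767437 were at -1.17 and -0.996 in phase 3. The run at 2039105 to 2044506 was at -0.66 or lower in phase 3, where 1 of 4 members was not well above background in the biofilm, and at -1.78 or lower in phase 4, where 2 were not. In phase 4, a run of 3 on the minus strand at 2841210 to 2844647 was 67.7-fold higher in the biofilm (6.08 on the log2 scale, against 0.57, 0.80 and 0.18 in phases 1, 2 and 3), and a run of 3 at 319860 to 322850 was higher by 4.60. A run of 5 on the minus strand at 3054432 to 3057918 had a difference of -3.19 in phase 4, and a run of 5 on the plus strand at 1541930 to 1545434 had -1.95.

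**Figure D2:**
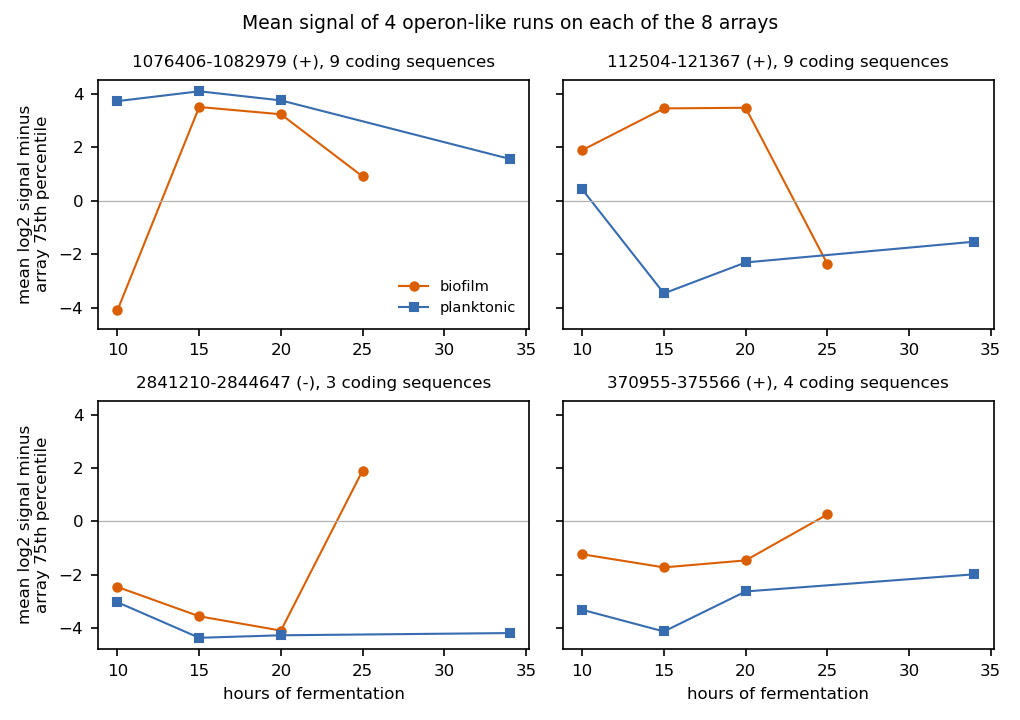
Mean log2 signal, relative to the 75th percentile of each array, of 4 operon-like runs against hours of fermentation, with 1 point per array (circles for biofilm, squares for planktonic cells). The run 1076406 to 1082979 lies at -4.09 on the biofilm array of 10 h and between 0.91 and 4.10 on the other 7 arrays.

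Over single features, 183, 322, 192 and 377 were at least 2-fold higher in the biofilm in phases 1 to 4, and 169, 162, 77 and 134 were at least 2-fold lower. These counts compare pairs of arrays and carry no test. Higher features made up 52.0%, 66.5%, 71.4% and 73.8% of the 2-fold differences, and this share depended on the scaling in the first 3 phases. In phase 1 it was 64.6% with normexp correction, 46.4% with quantile normalization, 49.1% with the authors' value table and 47.3% with the percentile over all non-control spots. In phase 2 these settings gave 80.8%, 45.7%, 49.9% and 28.0%, and in phase 3 they gave 74.3%, 59.5%, 62.8% and 50.6%. In all 4 phases alike, 379 features were higher and 795 lower, without a test. The median difference was -0.06, -0.10, -0.02 and -0.15 in phases 1 to 4, and such counts move with it. The percentile over all non-control spots moved the median difference of all features from -0.06 to -0.19, a shift of -0.14. Across features, which are not independent replicates, the differences of phases 2 and 3 had Pearson's r = 0.64 and those of phases 1 and 2 had r = 0.46. The remaining 4 of the 6 pairs of phases had r = 0.17 for phases 1 and 3, 0.11 for phases 1 and 4, 0.28 for phases 2 and 4 and 0.26 for phases 3 and 4.

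The second comparison asked what changed with the phase in both modes together, with 2 arrays per phase. The F-test over phases passed for 365 of 3725 features. Against phase 1, 0 features rose and 2 fell in phase 2, with 506 at an unadjusted p under 0.05. In phase 3, 55 rose and 22 fell, and in phase 4, 388 rose and 258 fell (limma, adjusted p under 0.05). Both arrays of phase 1 lay in slide row 2 and both of phase 2 in slide row 1. Phase 2 against phase 1 therefore cannot be told apart from slide row in this fit. A run of 3 coding sequences on the plus strand (1475839 to 1477003) rose 51.5-fold from phase 1 to phase 4, by 4.94 in the biofilm and 6.43 in planktonic cells on the log2 scale (run mean in limma, adjusted p = 0.00927). Runs of 3 at 1505779 to 1508406 and 3043298 to 3046121 rose 19.8-fold and 8.84-fold (run mean in limma, adjusted p = 0.0248 and 0.0148). These are means over unequal modes: the former rose by 5.71 in the biofilm and 2.90 in planktonic cells on the log2 scale. The latter rose by 2.71 and 3.58. The run of 3 on the minus strand at 1297877 to 1302116 fell at least 35.4-fold, since all 3 members were not well above background in phase 4 in both modes (adjusted p = 0.0191). A run of 5 on the plus strand at 1606339 to 1609286 fell at least 20.2-fold, with 3 members in the biofilm and 2 in planktonic cells not well above background in phase 4 (adjusted p = 0.00927). The run of 6 at 2152964 to 2158701 fell at least 23.3-fold (run mean in limma, adjusted p = 0.0169), by 3.78 in the biofilm and 5.30 in planktonic cells on the log2 scale. The adjusted p of these falling runs came from the run mean in limma on the signals as measured. The bounds themselves were not tested. Camera with the preset correlation called 13 runs up and 37 down, of which 13 and 27 also passed with the run mean in limma, where 22 rose and 27 fell. With an estimated correlation camera called 0 runs, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.954. That setting recovered 0 of 20 simulated runs for the mode difference. With slide row as a further block, 164 features rose and 165 fell from phase 1 to phase 4. Without the phase 2 pair 225 rose and 198 fell, and without the phase 3 pair 227 rose and 157 fell. The F-test passed for 143, 223, 167 and 63 features without phases 1, 2, 3 and 4 in turn.

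The third comparison asked whether the biofilm difference itself changed between phases 1 and 2 and phases 3 and 4. The interaction passed for 0 of 3725 features in limma, with a smallest adjusted p of 0.409 and 301 features at an unadjusted p under 0.05. The limma fit with trended and robust variances also called 0. Camera with the preset correlation called 14 runs up and 14 down. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), a setting that recovered 0 of 20 simulated runs for the mode difference. The run mean in limma called 0 (13 at an unadjusted p under 0.05, smallest adjusted p 0.786). The run 3824260 to 3828397 was lower in the biofilm in all 4 phases, with a late minus early difference of 1.35. This change passed camera at the preset correlation (adjusted p = 0.000969), but not at an estimated one (adjusted p = 0.995). It did not pass with the run mean in limma either (adjusted p = 0.786). Slide row and this change cannot be told apart in these arrays.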

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

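The test against background for the run at 1076406 to 1082979 was chosen after its signals were seen, and the test of neighbouring spots before. The 4 phase differences of 30 named runs were searched for 1 phase far from the others. Chance marks about 1 in 20 such sets, and because runs were named for large differences in 1 phase, more than that can arise.

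The run of 9 coding sequences at 1076406 to 1082979 stood furthest apart: the gap of phase 1 to the nearest other phase took 0.981 of the whole range of its differences. Its probes lay scattered over rows 2 to 191 and columns 8 to 67 of the array, and the 72 nearest other spots had a median phase 1 difference of -0.11 with a standard error of 0.095, which argues against a local defect of the array surface. All 9 probes were well above background on the biofilm array of phase 1, with a median signal of 108, which argues against a reading at the background floor. The run was bright on the other 7 arrays. A difference of growth mode in acidogenesis stays open as an untested explanation, as does a difference of that 1 culture, since the low value rests on a single array.

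The run at 2841210 to 2844647 was set apart by phase 4, with a gap of 0.894 of its range and a difference of 6.08 there. The run at 1505779 to 1508406 was also set apart by phase 4, with a gap of 0.890 of its range and a difference of 2.47. The run at 2763544 to 2767437 was higher in the biofilm in phases 1 and 2 and lower in phases 3 and 4, although its phase 1 difference of 0.03 became -0.01 with the percentile over all non-control spots. This is a change of -1.85 that did not pass with the run mean in limma. The run at 3054432 to 3057918 did the same, with a change of -2.39 that did not pass with the run mean either. Both changes passed camera at the preset correlation (adjusted p = 0.00315 and 0.00890), but not at an estimated one (adjusted p = 0.995 for each). Slide row and these changes cannot be told apart.

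Of the 4075 probes without coordinates, 682 (16.7%) were well above background on all 8 arrays, although they entered none of the fits. Their median signal was 35.3, and 21 of them were brighter than the median of the probes with coordinates. Their median biofilm minus planktonic differences were 0.24, 0.82, 0.34 and -0.27 in phases 1 to 4. The scaled median of all spots without coordinates, most of them not well above background, moved the same way. It was -8.43 in the biofilm and -9.27 in planktonic cells in phase 2, and -9.10 and -8.44 in phase 4. These differences therefore cannot be told apart from a shift of the background level.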

How the results depend on the processing

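The percentile over all non-control spots, the run mean in limma and every alternative for runs were chosen after the data were seen. The number of features higher in the biofilm was 8, and between 8 and 12 under normexp, quantile normalization, the authors' value table, either filter, the brightest probe and trended variances, with the 8 features called under each. It became 14 higher and 2 lower with the percentile over all non-control spots, 4 without the phase block, 0 with slide row as a further block and between 0 and 2 when a phase pair was left out. Leaving out a pair or adding a block leaves fewer degrees of freedom. All 8 kept a positive difference under every alternative run. The alternatives reuse the same arrays, on which all 8 were higher in every phase, so the kept direction adds no support. The interaction called 0 features under every alternative run for it, and the median correlation of phase differences stayed between 0.256 and 0.293. Of 1265 values of named features and runs under alternatives, 17 changed sign, and the largest of these was 0.76 in size as reported. They include the phase 4 differences of the runs at 1274369 to 1277118 and 1290943 to 1294722 under normexp.

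Leaving out a phase pair gave between 63 and 223 features by the F-test, between 225 and 227 rises and between 157 and 198 falls of phase 4 against phase 1. With slide row as a block, 164 rose and 165 fell. Features at least 2-fold lower in phases 1 to 4 numbered 75, 66, 38 and 75 with normexp, and those higher in phase 3 numbered 110. In phase 2 the lower ones numbered 323 with quantile normalization, 279 with the authors' value table and 589 with the percentile over all non-control spots, which also gave 131 in phase 3. At 3-fold, 77, 198, 67 and 219 were higher and 41, 18, 19 and 34 lower. For runs in the mode comparison, the filter on all 8 arrays gave 16 higher, normexp 26 lower and slide row 8 lower. With an estimated correlation 0 runs were called in either comparison and direction, a test that recovered 0 of 20 simulated runs. The run mean in limma called 0 higher and 0 lower for the modes, and 22 rises for phase 4. The cause of these changes was not tested. The phase block already pairs the modes, and no further pairing was possible because replicate numbers pair nothing beyond the phases. Dim features limit the falls to phase 4, since a signal not well above background gives only a bound.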

Other observations

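The tests of a time lag, of the scaling behind it, of signal level and of shifts along the chromosome were chosen after the patterns were seen; the tests of other splits and of gene dosage were fixed before. On the minus strand of record A, 7 neighbouring runs between 1272479 and 1309204, a stretch of 36.7 kb with 30 measured coding sequences, were looked at together. Their mean signal was higher in the biofilm by 0.92 in phase 1 and 2.98 in phase 2. In phase 4, 17 of the 30 members in the biofilm and 13 in planktonic cells were not well above background, so the mean change from phase 1 to phase 4 is only bounded, at -3.27 or lower in the biofilm and -2.61 or lower in planktonic cells. Of the 7 runs, 5 passed for this change with the run mean in limma and 6 with camera at the preset correlation. With an estimated correlation camera passed 0 of them (adjusted p = 0.954 for each). That setting recovered 0 of 20 simulated runs for the mode difference. The run at 1272479 to 1273495 passed neither, with a change of -1.04. This stretch was chosen after its values were seen.

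Runs at least 4-fold higher in the biofilm numbered 2, 15, 6 and 14 in phases 1 to 4, and those at least 4-fold lower 2, 0, 0 and 1. All 6 of phase 3 were also among the 15 of phase 2, against 0.312 by independence of the runs, while phases 3 and 4 shared 0. Phases 2 and 4 shared 2 against 0.729, phases 1 and 2 shared 1 against 0.104, and phases 1 and 4 shared 1 against 0.0972. Phases 1 and 3 shared 0. Several of the 15 runs of phase 2 are neighbours in the minus-strand stretch described above, so the runs are not independent and these references are rough. Besides the runs already described, those at 3496696 to 3498958, 1131720 to 1134179 and 1008240 to 1010481 were higher in phases 2 and 3, by 3.47 and 3.64, 2.22 and 2.62, and 2.38 and 2.02. In phase 4, the run at 2187183 to 2191627 was higher by 3.47.

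The count of 8 features was set against the other ways to part each of the 4 phase pairs. There are 8 such splits, too few for a share under 0.05. The real one gave 8 features, 1 split of the 8 gave that many, and the highest of the others gave 0. For runs called by camera with the preset correlation, the real split gave 41 and the highest of the others 55, and 5 of the 8 splits gave at least 41.

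On the first principal component, the biofilm arrays of phases 1 to 4 lay at -36.0, -28.2, 1.33 and 31.2 and the planktonic ones at -27.4, 0.67, 15.2 and 43.4. A candidate explanation is that biofilm cells sit earlier in the course than planktonic cells of the same phase. In phase 4 the biofilm array was taken at 25 h and the planktonic one at 34 h. A lag of the mode and the earlier hour cannot be told apart there. The differences of each phase were correlated across features with planktonic changes between other phases, which share no array with them. The median of the 12 correlations was -0.11, from -0.43 to 0.21, and 7 of 12 lay below 0, short of the 10 that had been asked for. All 6 that used the planktonic array of phase 1 lay between -0.43 and -0.21, and the other 6 lay between -0.01 and 0.21. All values of -0.21 or lower thus rest on that 1 array, and the lag stays open. Quantile normalization gave a median of -0.096 but moved no correlation by more than 0.034, so it was no test of the scaling.

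In phases 1 and 2 the biofilm difference was lower the further a feature lay from the start of record A. That start was assumed to be the replication origin of a circular chromosome, which the files do not state. The rank correlations across features, which are not independent, were -0.13 and -0.14 on the right and left arms in phase 1 and -0.16 and -0.15 in phase 2, and on the weaker arm reached 0.153 in size. They were -0.02 and -0.03 in phase 3, and -0.06 and 0.06 in phase 4. The biofilm and planktonic arrays shared a slide row in phases 1 and 2 only. The contrast of these phases with phases 3 and 4 therefore cannot be told apart from slide row. The median difference of features within 0.493 Mb of the origin exceeded that of features as close to the opposite side by 0.18, 0.27, 0.06 and -0.00 in phases 1 to 4. Mean signal had rank correlations with distance of 0.05 and -0.03 on the right and left arms, and with it held constant the smallest of the 4 correlations of phases 1 and 2 was 0.132 in size. A signal that barely varies with distance, and in opposite directions on the arms, argues against signal level as the source. A share of 0.0223 of 717 circular shifts along the chromosome gave a value as large as that of phase 2 in the best of their 4 phases, which argues against chance placement of neighbours that vary together. A gene dosage gradient from replication could give such values. It remains a hypothesis, since each phase rests on 1 array per mode and no DNA was measured. The time lag left open above was not tested as a source of this gradient.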
